A study of Mus musculus with 2 samples.

How the data were processed

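The series profiled where PITX2 occupies the genome of the mouse heart after birth. PITX2 is a homeobox transcription factor with known roles in left-right patterning and in the atria. Chromatin came from whole hearts of mice aged 12 weeks, and the protein carried a FLAG tag, a short peptide that an anti-FLAG affinity gel captures. Per the labels' protocols, libraries for Ion Torrent sequencing were made from 10 to 50 ng of precipitated DNA, selected for fragments of about 100 to 250 bp and amplified over 15 PCR cycles. The finished libraries ran at about 170 to 220 bp. The series has 2 samples, 1 FLAG precipitate and 1 input (chromatin that was not precipitated), with 1 library in each group.

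The authors deposited 1 peak list, for the FLAG precipitate, and it was the only data file used here. It gives a position, a name, a score and a strand for each peak and has no header. HOMER 4.1 and the genome build mm9 are named in the submitters' processing notes, without a role. The aligner, the peak calling thresholds and the part the input played are not given in the sources used here. The score is the authors' own value per peak and its scaling is not given in the sources used here. It was used to rank and filter peaks within the list. A share of the summed score and an expectation with halved scores also took it as a quantity. Whether it is proportional to signal is unknown here. All deposited scores are whole numbers from 5 upwards, and 5 is shared by 50.4% of the peaks. The number of reads behind a peak, and the depth of either library, are unknown here. All intervals below cover counting error only. Neighbouring peaks are not independent, which makes counting intervals too narrow.

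Positions are given on mm9, counted from 1. The gene table at hand is of the GRCm38 assembly, and peaks lay beyond its last gene on 7 of the 20 chromosomes compared (the autosomes and X), so its coordinates were not applied to the peaks. No genome sequence of mm9 was used. Peaks were therefore not assigned to genes. The comparisons planned on promoters, annotation classes, gene lists and sequence motifs were not run, and the planned lists of ion channel, calcium handling, intercalated disc, sarcomere and other genes have no result here. By the rule fixed before the data were examined, peaks without an annotation are named by position: the 10 with the highest score and the 5 widest. All peaks have the same width, so the second part named none. Other regions named below were chosen after their values were seen.

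Chromosome lengths of mm9 were not at hand. The span from the first to the last peak of a chromosome took their place, a choice made after seeing the data. Peaks per Mb of span were compared in bins of 5 Mb, each chromosome against the bins of all others, by two-sided permutation tests of 100000 resamples with Benjamini-Hochberg adjustment over the 20 chromosomes. Their smallest possible p is 1e-05. The counts per chromosome were also set against 100000 multinomial draws in proportion to span. Clustering was tested with 1000 random placements of the peaks, each kept on its own chromosome, for which the smallest two-sided p is 0.002. Shares have exact Clopper-Pearson intervals at 95%, and densities exact Poisson intervals. Chromosomes Y and M were left out of densities and placements, which leaves 11272 peaks. The alternatives were peaks with a score above 5 (standing for the planned upper part of the list by score, since the median itself is 5), overlapping peaks merged, peaks within 10 kb of another counted once, no peaks of chromosomes Y and M, a score of at least 10, placement within a peak's own 1-Mb bin and leaving out the 4 densest windows of 100 kb. The last 3 were added after seeing the data, as was counting neighbours once for anything but clustering. The comparisons of scores between chromosomes, of crowded windows and of the surroundings of high-scoring peaks were also added then.

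The tests were tested on simulated data of 11272 peaks. Under uniform placement the clustering test passed 0.05 in 1 of 20 runs, and in 20 of 20 runs after 500 peaks were moved to 2 kb from another. The density test for X passed 0.05 in 1 of 20 runs under uniform placement and in 20 of 20 runs after X peaks were halved at random. These runs used fewer placements and resamples than the tests reported below. The density test was not tried on clustered peaks, so its false positive rate there is unknown. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.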

Results

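Genomic occupancy of FLAG-tagged PITX2 was measured by chromatin immunoprecipitation and sequencing in whole hearts of mice aged 12 weeks, with 1 precipitated library and 1 input library. The design pairs the precipitate with its input and asks where PITX2 sits in the heart after birth. The values below come from the authors' list of 11279 peaks for the precipitate, and how the input entered that list is not given in the sources used here. With 1 library per group there is no replicate check, and no p-value below describes variation between animals. Every value is a property of this list.

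Most peaks carried low scores. The authors' score ranged from 5 to 815, with a median of 5 and a 75th percentile of 7. The lowest score, 5, was given to 5686 peaks. A score of at least 10 was reached by 1068 peaks (9.47%), a score of at least 20 by 358 peaks (3.17%) and a score of at least 100 by 43 peaks (0.381%). The 10 highest peaks held 4.91% of the summed score of the list. Every peak was 162 bp wide and recorded on the plus strand, so width could not be related to score. No peaks overlapped, and the smallest distance between neighbouring centres was 268 bp.

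The highest score, 815, belonged to a peak on chromosome 12 at 3109901 to 3110062. Chromosome 9 held 3 of the next peaks in rank. These were a peak at 3024420 to 3024581 with a score of 570, a peak at 88448037 to 88448198 with a score of 458 and a peak at 3000463 to 3000624 with a score of 447. A second peak on chromosome 12, at 70462156 to 70462317, had a score of 401. Chromosome 5 carried a peak at 150059530 to 150059691 with a score of 383 and another at 114623095 to 114623256 with a score of 325. The remaining peaks of the first 10 lay on chromosome 13 at 9010968 to 9011129 (score 362), on chromosome 6 at 131327516 to 131327677 (score 312) and on chromosome 1 at 34047808 to 34047969 (score 285). Only the pair near the start of chromosome 9 had another peak within 10 kb, at 945 bp and 436 bp. The other 8 were between 10873 bp and 239046 bp from their nearest neighbour. The ranking covers listed peaks only. The running numbers in the authors' peak names skip the first 3 of chromosome 2, whose next number has a score of 186, and whether peaks stood there is unknown here.

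Peaks were spread unevenly over the chromosomes. Chromosome 11 carried the most, 949 peaks or 8.41% of the list (95% interval 7.91 to 8.94%), although it made up 4.62% of the total span. Its density of 7.99 peaks per Mb (7.49 to 8.52) was 1.72 times the median autosome's 4.64. Chromosome X carried 207 peaks or 1.84% of the list (1.60 to 2.10%), with 6.36% of the span. Its density of 1.27 peaks per Mb (1.10 to 1.45) was 0.38 times that of the lowest autosome, chromosome 14, which had 3.33 peaks per Mb. The autosomes lay between 3.33 and 7.99 peaks per Mb. Chromosomes 17 and 19 followed chromosome 11, with 6.04 and 5.62 peaks per Mb. These densities also count listed peaks only. Among the autosomes and X, the share of skipped numbers ran from 3.89% on chromosome 16 to 12.8% on chromosome 9, with 11.7% on chromosome 11 and 10.0% on X.

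The counts per chromosome departed from proportion to span (chi-square 1004, largest of 100000 multinomial draws 55.5, p = 1e-05, the smallest the draws can give). The draws treat peaks as independent, and clustering of peaks also raises this chi-square, so its p does not isolate differences between chromosomes. In bins of 5 Mb, chromosome 11 held 7.75 ± 5.68 peaks per Mb (SD over 23 bins) against 4.17 ± 3.11 in the bins of the other chromosomes (permutation test, adjusted p = 0.0002). Chromosome X held 1.19 ± 0.738 (SD over 32 bins) against 4.55 ± 3.35 (permutation test, adjusted p = 0.0002). No other chromosome passed after adjustment. Chromosome 17 came nearest, with 6.09 ± 4.07 peaks per Mb over 18 bins and an adjusted p of 0.154.

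**Figure D1:**
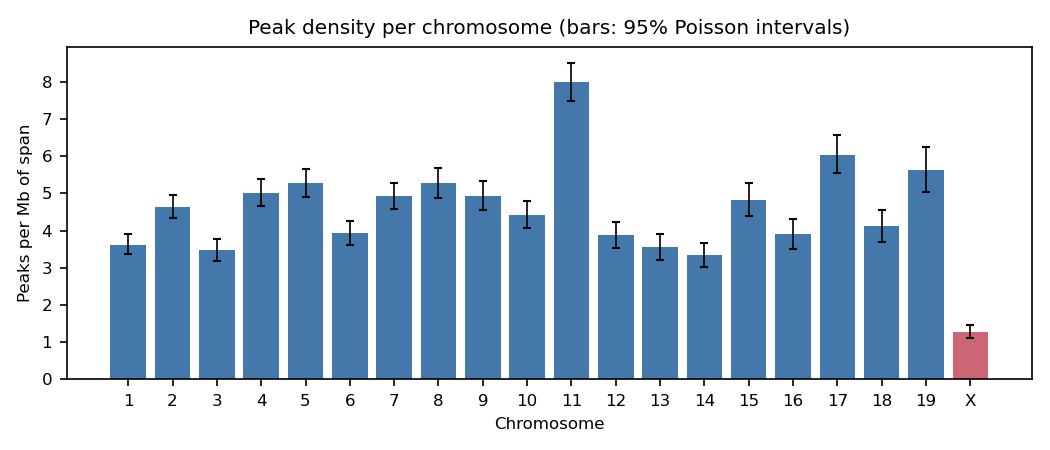
Peaks per Mb of span (vertical axis) for each autosome (blue) and X (red), with the exact 95% Poisson interval as error bars. Chromosome 11 stands highest at 7.99 peaks per Mb and X lowest at 1.27.

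Outside these chromosomes the list held 3 peaks on the mitochondrial chromosome and 4 on Y. The mitochondrial peaks lay at 15660 to 15821 (score 97), at 3290 to 3451 (score 19) and at 1955 to 2116 (score 17). The Y peaks lay at 606691 to 606852 and 2666680 to 2666841, both with a score of 7, and at 614761 to 614922 and 897466 to 897627, both with a score of 5. The latter score is the lowest in the list.

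Peaks lay closer together than random placement over the span of each chromosome would put them. Sequence in which no peak could be called was not left out of the placements, so part of the difference may come from it. The median distance from one peak to the next was 82346 bp, against 148563 bp on average over 1000 placements on the same chromosomes (lowest 144022, permutation p = 0.002, the smallest the placements can give). Another peak lay within 10 kb of 21.1% of peaks, against 9.07% of placed peaks (highest 10.2%, permutation p = 0.002). When peaks were placed only within their own 1-Mb bin, the placed share rose to 15.4% (highest 16.7%, permutation p = 0.002). The observed share was thus 2.33 times that of placement along the chromosome and 1.37 times that of placement within the bin.

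At the scale of megabases, 42 windows of 1 Mb held at least 20 peaks each, 995 peaks in all. No more than 2 such windows arose in any of 1000 placements. These windows lay on 16 chromosomes. Chromosome 11 held 11 of them and X held 0. The most crowded window, from 3 Mb on chromosome 11, held 41 peaks, and the most crowded window in any placement held 24. Next came a window on chromosome 8 with 29 peaks between 73029703 and 73988581. A window on chromosome 7 held 28 peaks between 52004072 and 52996466, with a highest score of 83. On each of chromosomes 17 and 19 a window held 27 peaks. Chromosome 10 had a run of neighbouring windows with 28 peaks between 79017695 and 79998695 and 27 peaks between 80005377 and 80970918. Chromosome 11 had a similar run from 100062455 to 101992819, with 27 peaks in each of its windows, and further windows of 27, 25 and 25 peaks from 115043776 to 117964484. The median score in the chromosome 8 and 10 windows was 6.

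The longest stretch between neighbouring peaks was 7.57 Mb, on chromosome 7 from 39013359 to 46584278. Chromosome X held 4 of the 10 longest. The longest of these measured 7.42 Mb, between 26228027 and 33652155. Among 129 stretches of at least 2 Mb without a peak, 25 were on X. How much of these stretches reads could map to was not examined.

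**Figure D2:**
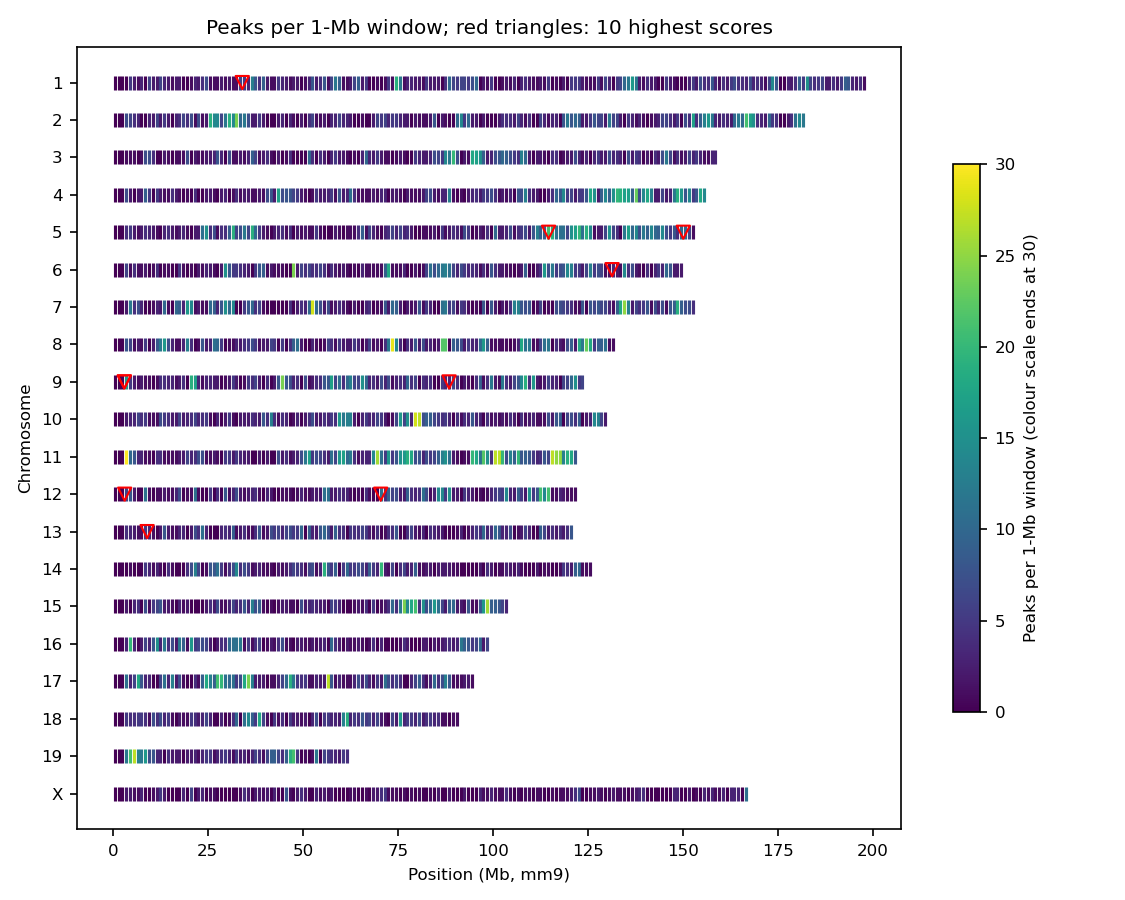
Peaks per window of 1 Mb (colour, scale ending at 30) along the autosomes and X (position in Mb on mm9), with the 10 highest-scoring peaks as red triangles, of which a pair near the start of chromosome 9 overlaps. The crowded windows, among them those of chromosomes 8, 10 and 11, are bright, and X is dark along its length.

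At the scale of 100 kb, 3 windows stood out by number. The window at the start of chromosome 11 held 24 peaks between 3023849 and 3093377, with a median score of 14.5. A window on chromosome 6 held 15 peaks between 47605021 and 47698650 with a median score of 25, and the next window on that chromosome held 8 peaks between 47702820 and 47728250 with a median score of 14.5. The window at the start of chromosome 9 held 15 peaks between 3000463 and 3038026 with a median score of 67. The fourth, near the end of X, held 9 peaks between 166417128 and 166446909 with a median score of 25. These median scores were all above the 5 of the whole list. Without the 4 densest windows, 20.7% of peaks still had another within 10 kb.

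The deficit on X depended on the score. Among peaks with a score of 5, X had 0.23 times the autosomal density (95% interval 0.19 to 0.29), from 88 peaks. For scores of 6 to 9 the ratio was 0.25 (0.20 to 0.32), for scores of 10 to 19 it was 0.47 (0.29 to 0.72), and for scores of 20 and above it was 0.92 (0.56 to 1.43), from 21 peaks. Of the X peaks, 10.1% had a score of at least 20, against 3.04% of autosomal peaks (Fisher's exact test, two-sided, p = 2.48e-06). The crowded window near the end of X supplied part of this. Without the 4 densest windows the X share was 7.58%, against 2.78% (Fisher's exact test, p = 0.00057), and the density ratio for scores of 20 and above was 0.72 (0.40 to 1.21).

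The share of peaks with a score of at least 10 was compared for each of the 20 chromosomes with all others. X had 20.8% against 9.24% (43 of 207 peaks, Fisher's exact test, adjusted p = 1.57e-05). Chromosome 6 had 14.3% against 9.19% (82 of 575 peaks, Fisher's exact test, adjusted p = 0.00131). With peaks within 10 kb of another counted once, the chromosome 6 share was 12.0% against 9.60% (Fisher's exact test, unadjusted p = 0.0745). Without the 4 densest windows of 100 kb, of which 1 is on chromosome 6, it was 12.0% against 8.80% (Fisher's exact test, unadjusted p = 0.0148). The adjoining window of 8 peaks, between 47702820 and 47728250, was kept, so the whole crowded stretch was not left out. No other chromosome passed after adjustment.

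High-scoring peaks had fewer score-5 peaks within 500 kb than those of middling score, while the share with any peak within 10 kb lay within counting error of theirs. Peaks with a score of 6 to 9 had on average 4.52 ± 3.52 peaks of score 5 within 500 kb (SD over 4523 peaks). Peaks with a score of 10 to 19 had 3.84 ± 3.32, those of 20 to 49 had 3.30 ± 3.32 and those of 50 and above had 3.22 ± 3.49. No score-5 peak lay within 500 kb of 9.44% of peaks scored 6 to 9 (95% interval 8.60 to 10.3%), of 22.9% of those scored 20 to 49 (17.9 to 28.5%) and of 24.2% of those scored 50 and above (16.2 to 33.9%). These means and shares pool the autosomes and X. X had few score-5 peaks and a larger share of high scores, which adds to the trend. To hold the chromosome fixed, scores of 6 and above were permuted within chromosomes 10000 times. The mean over peaks scored at least 20 was 3.28, below the central 95% of the permuted means, 3.78 to 4.42 (permutation p = 0.0002, the smallest the permutations can give). Within 10 kb, another peak of any score lay near 23.5% of peaks scored 6 to 9 (22.3 to 24.8%), 25.4% of those scored 10 to 19 (22.2 to 28.7%) and 23.7% of those scored at least 20 (19.4 to 28.5%), and near 18.5% of those scored 5 (17.5 to 19.6%). These shares were not recomputed without the 4 densest windows of 100 kb. Leaving those out cuts the peaks scored at least 20 on the autosomes and X from 357 to 321.

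**Figure D3:**
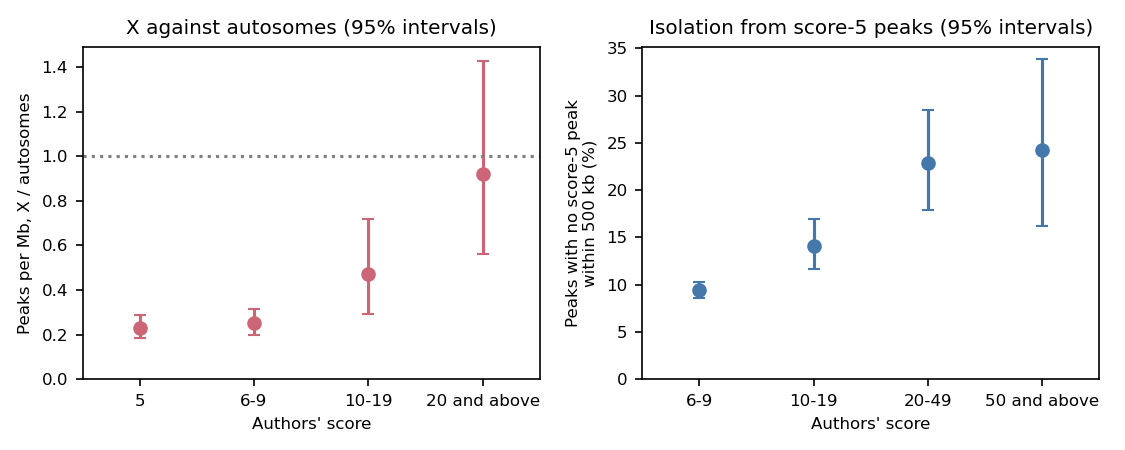
Left, density of peaks on X divided by that on the autosomes by class of the authors' score, with the dotted line at equal density. Right, share of peaks with no score-5 peak within 500 kb by score class, and both panels show 95% intervals. The X ratio runs from 0.23 at score 5 to 0.92 at 20 and above, and the isolated share from 9.44% to 24.2%. The isolated share pools the autosomes and X.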

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

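The names the authors gave their peaks carry a running number per chromosome that no comparison above used, and 1116 of the 12395 numbers up to each chromosome's highest belong to no peak of the list. The score never rose along the numbers. Of the missing numbers, 319 were in the lower numbers up to the midpoint of their chromosome's numbering, where listed peaks score higher, and 797 in the numbers after it. The first 3 numbers of chromosome 2 are among them, and its number 4 has a score of 186. So are all numbers between 2 and 10 of chromosome 17, which have scores of 130 and 49. Some numbers between 9 and 22 of chromosome 9, with scores of 109 and 43, are missing too. Whether the skipped numbers stand for peaks left out of the list is unknown here. The missing share was 11.7% on chromosome 11, 12.8% on chromosome 9 and 3.89% on chromosome 16.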

How the results depend on the processing

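Clustering kept its direction and its p of 0.002 against random placement under every alternative run. The median gap lay between 0.55 and 0.86 times that of placed peaks, and the share within 10 kb between 1.37 and 3.18 times. Counting neighbours within 10 kb once fixes that share at 0, so it has no value there. With a score above 5, the list shrank to 5593 peaks, the share on chromosome 11 was 9.10% and that on X 2.13%. With neighbours within 10 kb counted once, the share on chromosome 11 was 7.84%, and the chromosome 6 share of peaks scored at least 10 was 12.0% against 9.60% elsewhere and no longer passed (Fisher's exact test, unadjusted p = 0.0745). Without the 4 densest windows it was 12.0% against 8.80% (Fisher's exact test, unadjusted p = 0.0148). That setting kept the adjoining chromosome 6 window of 8 peaks, and its p was not adjusted over the chromosomes. For scores of at least 10, the share on X was 4.03% and X stood at 0.96 times the lowest autosome. The larger share of scores of at least 10 and of at least 20 on X passed in both of its alternatives, as did the lower number of score-5 peaks within 500 kb of high-scoring peaks (permutation tests, highest p 0.002). The causes of these shifts were not tested. No paired analysis was possible because each group has 1 library. The settings foreseen for promoters, annotation classes, gene lists and motifs were not run, since no mm9 annotation or sequence was used. The unknown depth limits what a score of 5 means, and 50.4% of the list has it.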

Other observations

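None of the tests below was planned before the data were examined. Those on X and on crowded chromosome starts were chosen only after the counts they use had been seen, and the test on score-5 peaks around high-scoring peaks before its own value was seen.

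Chromosome X carried fewer peaks per Mb than any autosome, and the deficit was mostly in low scores. With peaks within 10 kb counted once, X still had 0.39 times the density of the lowest autosome (95% interval 0.32 to 0.47). Counting clusters at that scale once thus left the deficit in place. Only 21.1% of all peaks had another within 10 kb, so this count could hardly have closed it and describes rather than tests. This count kept 9963 of 11272 peaks and left crowding over megabases in place, so crowding at that larger scale was not tested. Signal halved on X in all cells, with a score proportional to it, would leave 69.4 X peaks (95% Poisson range 54 to 86), and 207 were present. The scaling of the score is unknown, so this comparison cannot decide on halved signal. A lower X signal in all or part of the material, poorer read mapping on X and a lower number of true binding sites there remain open and untested. The sex of the animals was not used here.

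High-scoring peaks may be partly another class of site than the low-scoring majority. If they were placed as the others, peaks scored at least 20 would have between 3.78 and 4.42 score-5 peaks within 500 kb, and they had 3.28. With neighbours within 10 kb counted once the value was 2.83 against a permuted mean of 3.24 (permutation p = 0.002). The smaller deficit of high scores on X goes the same way (ratio 0.92, or 0.72 without the 4 densest windows). Within 10 kb they had neighbours about as often as peaks scored 6 to 9 (23.7% and 23.5%). That share was not recomputed without the 4 densest windows, so how far it rests on them is unknown here. Whether high-scoring peaks are strong PITX2 sites or positions of raised background cannot be read from a peak list without the input's signal, so both stay open.

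The first 100 kb after 3 Mb, where autosomal peaks begin, held 51 peaks on 7 of the 19 autosomes, against 8.75 under even spread, and 2 of the 10 highest peaks. The highest peak of the list, on chromosome 12 at 3109901 to 3110062 (score 815), lay just past this region and is not counted in it. Nor is a peak on chromosome 6 at 3151438 to 3151599 (score 57), which had another peak 326 bp away. Far ends of the chromosomes were not examined, so only a trait of every autosome's start can be judged. It is argued against, since only 7 of the 19 autosomes had a peak in this region. Chromosomes 11, 9 and 17 alone held 24, 15 and 6 of the 51. Sequence with more copies in the animals than in the build would raise scores as well as numbers. The median score there was 17 against 5 for the other autosomal peaks, 12.5 without chromosome 9 and 35 without chromosome 11. The scores had been seen before the region was chosen and were raised on chromosomes 9, 11 and 17, while the other 4 autosomes had medians from 5 to 7, so this explanation stays open, the repeat content was not examined, and no biological explanation was tested.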
